A study of Homo sapiens with 28 samples.

How the data were processed

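EPC2 esophageal epithelial cells were seeded at high confluency 1 day before treatment in KSFM medium and treated for 6 h, per the labels. There were 28 samples: 12 RNA sequencing samples (paired-end), 3 for each of 4 treatments, and 16 ChIP-seq samples (single-read), 1 for each treatment of 5 factors and marks. The labels do not say whether the 3 RNA samples of a treatment were separate cultures, nor which form of vitamin D was given. Chromatin was fixed with paraformaldehyde, sheared by Covaris sonication and immunoprecipitated on an automated system, per the labels.

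Trim Galore, STAR, SAMtools, Bowtie and MACS2 and the builds GRCh37 and hg19 are named in the submitters' processing notes; their versions, settings and roles are not given in the sources used here. The RNA files were 4 tables of 23533 genes with 1 RPKM value per group, per the file headers. Their log2 fold changes are the authors' deposited values, and correlated with the log2 ratio of the RPKM columns at 0.993 to 0.997. Their p-values and adjusted p-values are deposited by the authors, and the test that made them is not given in the sources used here. Genes with an adjusted p of 1 were treated as not tested. The summed RPKM per group was 388972 untreated, 383127 with IL-13, 391648 with vitamin D and 377254 with both. RPKM does not give read depth, so the precision that depth allows in single samples is unknown here, and no spread between samples could be computed.

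The ChIP files were 1 peak list per library. The pileup is a signal, the height of stacked fragments at the summit, per the file headers, and is not scaled to a common depth by the authors. Fold enrichment was made by the authors' peak caller, per the file headers. It was read here as a ratio of pileup to background, with 1 added to each. The -log10 p and -log10 q values were deposited by the authors. Use of a control library is not given in the sources used here. The background of each library was computed back from pileup and fold enrichment as a relative measure of depth; it was nearly constant in the STAT6 and histone libraries and varied in the VDR libraries. Only 0.0955% of VDR pileups with vitamin D were whole numbers, so that library had been scaled, and its pileups were not compared with others. Mitochondrial peaks were left out. Summits were merged into regions by shared start and end.

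The RNA table named for IL-13 against the combination holds vitamin D against the combination. Its first column equals the vitamin D values for all 23533 genes, and its fold changes correlate at 0.995 with the ratio to vitamin D and at 0.00328 with the ratio to IL-13 (10928 genes). It was used as vitamin D against the combination. The combination against IL-13 was derived gene by gene as the combination against untreated minus IL-13 against untreated. Standard errors were derived from each deposited fold change and p-value; they are upper bounds where p is listed as 0. The derived comparison's variance was taken from those of the 4 tables, with their mean as a floor. It subtracts the variance of vitamin D against untreated, so its errors need not be upper bounds. The difference between the IL-13 effects with and without vitamin D came from 2 tables that share no library, and its variance is their sum. Both were tested with z tests, adjusted by Benjamini-Hochberg at 0.05 over 14734 genes. The 4 tables disagreed by over 0.5 on the log2 scale for 11 genes, TNFAIP6 by 6.14 and ADRA1B by 1.02 among them, which were left out of these tests, a choice made after the tables were seen. These tests were run on simulated data. The derived comparison recovered 70% of changes of 0.5 and 97% of changes of 1, with 6 false calls among 173. The difference of effects had 7 false calls among 149. With no spread between samples at hand, the simulations could not check whether the derived standard errors are right.

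17 gene lists were tested. They were the IL-13 response of esophageal epithelium, vitamin D receptor targets, vitamin D metabolism and receptor, IL-4 and IL-13 receptor and JAK-STAT pathway, epithelial differentiation and cornified envelope, basal epithelial cells, cell junctions, proteases and protease inhibitors, cytokines and chemokines, NF-kappaB response, interferon response, cell cycle, cholesterol synthesis, immediate early and stress response, and fibroblast, leukocyte and endothelial markers. The IL-13 response and VDR target lists hold genes known from earlier work to move with these treatments. The median log2 of a list was placed among 10000 random lists of the same size matched on expression in 20 bins, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. The permutation p is across genes, which are not independent replicates, and does not measure spread between samples. Genes of a list may move together, which the random lists do not allow for. Calls were also adjusted over the list alone. In simulated data all lists of 30 genes moved by 0.3 were recovered, and 3 of 100 unmoved lists were called.

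Named genes follow a rule fixed beforehand: in each comparison the 6 largest rises and 6 largest falls among called genes at 1 RPKM or more, up to 3 called members of each list, and CCL26, CAPN14, SERPINB3, CISH, CYP24A1, VDR, STAT6 and IL13RA2 always. In the derived comparison and the difference of effects the 6 genes of smallest adjusted p in each direction were named. Other list members given as examples were chosen after their values were seen. Some items that this rule names are not reported here. Named regions were the 5 of largest fold enrichment that overlapped no untreated region, and those assigned by the authors to a named gene.

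Regions were compared by an overlap of at least 1 base. Histone pileup ratios were divided by their median over shared regions, and compared with 10000 sets of regions matched on untreated pileup. Genes at 1 RPKM or more were scored for a region within 10 kb of the start, and tested with two-sided Fisher's exact tests, adjusted over 12 tests. A Mantel-Haenszel odds ratio over strata of H3K27ac was checked on simulated data, where 1.36 without strata became 0.971 for no effect. Co-occurrence of STAT6 and VDR was tested over the union of H3K27ac regions. Shared calls were set beside independent lists and beside 100 simulated draws with shared controls. Independent lists take every gene as equally likely to be called, and the draws held no changed gene. Neither thus gives the number of shared calls of unrelated responses. Alternatives changed the adjusted p to 0.01 and 0.1, the fold change to at least 2-fold, the expression filter, the median to a mean, the deposited fold change to the RPKM ratio with pseudocounts of 1 and 0.1, the distance to 2 and 50 kb, the fold enrichment to at least 5, the -log10 q to at least 5, the regions to the 1000 of largest fold enrichment, the overlap to at least 0.5 of a region, and the scaling and matching of pileups. Others were added after the data were seen: the derived comparison through the vitamin D table, centred fold changes, signs from RPKM ratios, larger standard errors, and regions absent from the untreated library. Motifs at summits were not analysed here. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.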

Results

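The series measured RNA, binding of STAT6 and of the vitamin D receptor VDR, and 3 histone marks in EPC2, an immortalised human esophageal epithelial cell line. Cells were left untreated or were given IL-13 at 100 ng/ml, vitamin D at 100 nM, or both, for 6 h. IL-13 is a type 2 cytokine that signals through the transcription factor STAT6, and vitamin D acts through the nuclear receptor VDR. RNA sequencing covered 12 samples, 3 in each of 4 groups. ChIP-seq covered 16 samples, 1 for each condition profiled. These were H3K4me3, H3K9ac and H3K27ac in all 4 treatments, STAT6 without and with IL-13, and VDR without and with vitamin D. The RNA tables used here held 23533 genes, 1 RPKM value per group and the authors' fold changes with p-values, so read depth per RNA sample is unknown and no spread between samples could be computed. At least 11165 genes reached 1 RPKM in each group, and the 10 most abundant genes, led by the keratin gene KRT6A, held 16.9% to 18.6% of the summed RPKM.

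The first comparison asked what IL-13 alone changed. In the authors' deposited table, IL-13 raised CAPN14, which encodes an esophageal calpain protease (chromosome 2, 31395922 to 31440411, hg19), by 5.08 on the log2 scale, from 10.2 to 358 RPKM, with an adjusted p listed as 0. The protease inhibitor gene SERPINB4 rose by 4.81 in the authors' deposited table, from 3.28 to 100 RPKM, and its neighbour SERPINB3 by 1.82, from 106 to 381 RPKM. SERPINB3 and SERPINB4 are near-identical paralogs, so their separate values are uncertain. The eosinophil chemokine gene CCL26 rose by 3.73 (adjusted p = 1.17e-88) in the authors' deposited table, from 0.02 to 7.85 RPKM. The size for CCL26 is uncertain, since the log2 ratio of RPKM with a pseudocount of 0.1 was 6.06. Epithelial differentiation genes moved the other way: in the authors' deposited table the cornified envelope gene IVL changed by -1.96 (adjusted p = 1.17e-259), from 50.3 to 12.7 RPKM, the suprabasal keratin gene KRT10 by -1.58 (adjusted p = 3.73e-298) and the desmosomal cadherin gene DSG1 by -0.98 (adjusted p = 6e-87).

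Among the other large rises in the authors' deposited table were TNFAIP6, which encodes a hyaluronan-binding protein, at 5.07 and SH2D1B at 4.15, each under 0.06 RPKM in untreated cells. The cytokine signalling inhibitors CISH and SOCS1 rose by 2.49 and 1.79 in the authors' deposited table, the repetin gene RPTN by 2.18, the desmosomal plakophilin gene PKP2 by 0.88 and VWF by 1.77. The largest falls in the authors' deposited table were ENDOU at -2.5, the retinol dehydrogenase gene DHRS9 at -2.11, IVL at -1.96, SDR9C7 at -1.77, CYP2C18 at -1.72 and the mucin gene MUC21 at -1.64. In the authors' deposited table the protease inhibitor gene SERPINB1 changed by -0.91 and the sugar phosphate exchanger gene SLC37A2 by -0.89. For the treatment's own components the authors' deposited table gave VDR 0.28, STAT6 -0.17, the decoy receptor gene IL13RA2 0.66 and CYP24A1, the vitamin D catabolic enzyme, -0.56 (adjusted p = 0.0116). Across genes, 3986 of 15172 tested passed an adjusted p of 0.05 in the authors' deposited table, 1862 higher and 2124 lower with IL-13. Of these 122 rose and 59 fell by at least 2-fold.

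Of the gene lists fixed before the data were examined, the IL-13 response list had 18 of 23 tested members up and 1 down (18 and 1 adjusted over the list alone). Its median was 1.65 on the log2 scale. The list of epithelial differentiation and cornified envelope genes had 2 of 52 up and 38 down (2 and 39 adjusted over the list alone), with a median of -0.47. The exceptions were RPTN and the late envelope gene LCE3D. Both medians lay outside all 10000 random lists of matched expression, with a permutation adjusted p of 0.00113 over 17 lists. Here and below this p is across genes, which are not independent replicates, and does not measure spread between samples. Smaller downward shifts passed the same permutation test for the cytokine and chemokine list (2 up and 15 down of 43, median -0.14, adjusted p = 0.0017; 2 and 17 adjusted over the list alone), where CCL26 was the main exception and IL1B fell by 0.48 in the authors' deposited table. The NF-kappaB list had 0 up and 9 down of 23 (0 and 10 adjusted over the list alone; median -0.13, adjusted p = 0.00595), with TNFAIP2 at -0.58 and BIRC3 at -0.34 in the authors' deposited table. The cholesterol synthesis list had 3 up and 13 down of 22 (3 and 13 adjusted over the list alone; median -0.16, permutation adjusted p = 0.00227). With the mean in place of the median the cytokine list (permutation adjusted p = 0.104) and the cholesterol list (0.0616) did not pass.

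The immediate early and stress list had 2 of 32 up and 16 down (2 and 17 adjusted over the list alone; median -0.11, permutation adjusted p = 0.00755). The cell cycle list had 2 of 38 up and 10 down (2 and 10 adjusted over the list alone; median -0.12, permutation adjusted p = 0.0119), and the interferon list 3 of 32 up and 11 down (3 and 13 adjusted over the list alone; median -0.08, adjusted p = 0.0198; 0.42 for the mean). The protease and protease inhibitor list had 8 of 39 up and 17 down (8 and 18 adjusted over the list alone), with a median of -0.17 (permutation adjusted p = 0.00113) but a mean of 0.10, with CAPN14, SERPINB3 and SERPINB4 among the genes that rose. Cell junction genes had 6 of 31 up and 14 down (7 and 15 adjusted over the list alone; median -0.11, permutation adjusted p = 0.00595). The permutation adjusted p was 0.324 over members at 1 RPKM or more and 0.38 for the mean. Basal epithelial genes were split, 8 up and 9 down of 20 (9 and 9 adjusted over the list alone; median -0.03, adjusted p = 0.846), with CD44 at 0.55, TP63 at 0.49 and KRT15 at -0.51 in the authors' deposited table. The receptor and JAK-STAT list (5 up and 5 down of 24, the same numbers adjusted over the list alone) had a median of -0.02 and a mean of 0.17 (permutation adjusted p = 0.411 and 0.0413). Vitamin D receptor targets (8 up and 11 down of 28, as adjusted over the list alone) had a median of -0.07 (permutation adjusted p = 0.085). Vitamin D metabolism genes (3 up and 5 down of 15, as adjusted over the list alone) had a median of -0.05 and a mean of 0.03 (permutation adjusted p = 0.32 and 0.693).

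Few markers of other cell types could be tested. Of the fibroblast markers 0 of 11 rose and 2 fell (0 and 2 adjusted over the list alone; median -0.06, adjusted p = 0.529), and of the leukocyte markers 1 of 3 rose, CD14 at 0.40 in the authors' deposited table (1 up and 1 down adjusted over the list alone; median -0.04, mean 0.09, adjusted p = 0.669). Endothelial markers had 2 of 5 up and 0 down, VWF at 1.77 and the tight junction gene CLDN5 at 0.57 in the authors' deposited table (2 and 0 adjusted over the list alone; median 0.37, adjusted p = 0.00204).

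**Figure D1:**
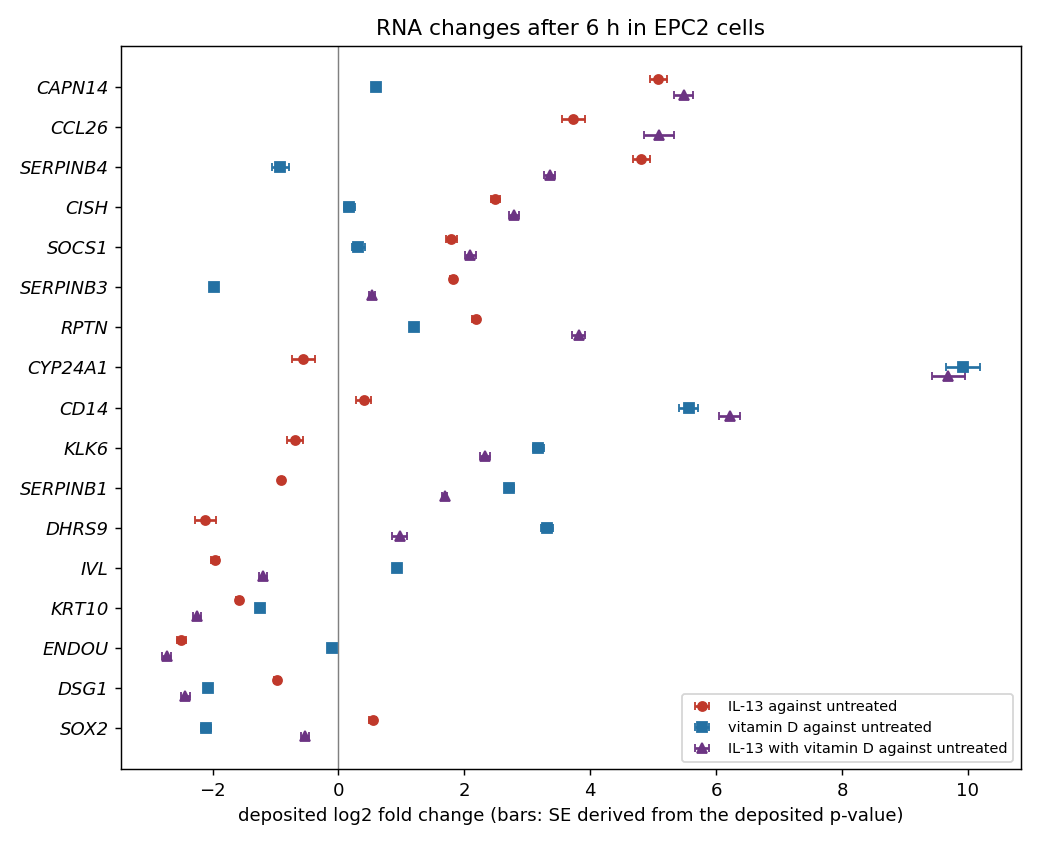
Log2 fold changes against untreated cells from the authors' deposited tables for 17 named genes; points are the 3 treatments and bars 1 standard error derived from the deposited p-value (an upper bound where p is listed as 0), and a treatment in which a gene was not tested is left out. CAPN14 stands at 5.08 with IL-13 and 5.48 with both, and CYP24A1 at 9.92 with vitamin D and 9.69 with both.

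The next comparison asked what vitamin D alone changed. CYP24A1 (chromosome 20, 52769988 to 52790516), whose enzyme degrades vitamin D and which is a classical VDR target, rose by 9.92 on the log2 scale in the authors' deposited table, from 0.48 to 560 RPKM. The pattern recognition receptor gene CD14 rose by 5.57 in the authors' deposited table, from 2.62 to 132 RPKM, the IL-33 receptor gene IL1RL1 by 4.36 (adjusted p = 1.88e-226) and FOS by 3.39. DHRS9 at 3.31 and the transporter gene SLC6A12 at 3.25 followed in the authors' deposited table. The kallikrein protease gene KLK6 rose by 3.18 and the protease inhibitor gene SERPINB1 by 2.71, from 64 to 407 RPKM, in the authors' deposited table. The largest falls in the authors' deposited table were the retinol-oxidising alcohol dehydrogenase gene ADH7 at -2.33 (adjusted p = 3.69e-101), the progenitor transcription factor gene SOX2 at -2.10 (adjusted p = 6.08e-154), KLRG2 at -2.09, DSG1 at -2.08, SERPINB3 at -1.97 and the estrogen sulfotransferase gene SULT1E1 at -1.81.

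Further rises in the authors' deposited table were the keratin gene KRT4 at 1.96, the claudin gene CLDN7 at 1.54, TGFB1 at 1.37, EMP1 and IL1B at 0.98 each, the phosphatase gene PTPN1 at 0.89 and CAPN14 at 0.59 (adjusted p = 3.18e-36), from 10.2 to 14.8 RPKM. KRT10 changed by -1.25, VDR by -0.20 and STAT6 by -0.11 in the authors' deposited table. CISH at 0.17 (adjusted p = 0.119) and IL13RA2 at -0.01 (adjusted p = 0.972) did not pass the threshold in the authors' deposited table, and CCL26 was not tested there, at 0.02 RPKM in both groups. In all, 4939 of 15177 tested genes passed in the authors' deposited table, 2649 higher and 2290 lower with vitamin D. Of these 189 rose and 69 fell by at least 2-fold.

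Vitamin D receptor targets had 25 of 30 tested members up and 3 down (25 and 3 adjusted over the list alone), with a median of 0.76 and a permutation adjusted p of 0.00085. Their exceptions in the authors' deposited table were TNFAIP3 at -0.39, CDKN1A at -0.25 and VDR. The NF-kappaB list had 3 of 23 up and 13 down (3 and 13 adjusted over the list alone; median -0.24, adjusted p = 0.00085), with BIRC3 at -1.24 and the inhibitor gene NFKBIA at 0.66 in the authors' deposited table. The interferon list had 5 of 32 up and 17 down (6 and 17 adjusted over the list alone; median -0.11, adjusted p = 0.00136), with CXCL10 at -0.71 and IFIT3 at -0.42 in the authors' deposited table, and cholesterol synthesis had 4 of 22 up and 12 down (5 and 12 adjusted over the list alone; median -0.09, adjusted p = 0.00085). Immediate early and stress genes had 17 of 32 up and 10 down (19 and 11 adjusted over the list alone; median 0.23, permutation adjusted p = 0.00085, and 0.0519 for the mean). Among them FOS, JUNB at 0.80 and DUSP5 at 1.03 rose and DDIT3 at -0.83 fell in the authors' deposited table.

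Differentiation genes divided with vitamin D, 17 up and 20 down of 52 (19 and 20 adjusted over the list alone), with a median of -0.03 (permutation adjusted p = 0.00453) and a mean of 0.02 (permutation adjusted p = 0.292). KRT4, IVL at 0.93 and the cornulin gene CRNN at 0.84 rose, and KRT10, KRT1 at -1.52 and TGM3 at -0.86 fell in the authors' deposited table. The vitamin D metabolism list had 3 of 15 up and 6 down (3 and 6 adjusted over the list alone), with a median of -0.10 (permutation adjusted p = 0.0442) and a mean of 0.61 that CYP24A1 set. Basal epithelial genes had 6 of 20 up and 7 down (6 and 7 adjusted over the list alone; median -0.03, permutation adjusted p = 0.0323). Random lists had medians of 0.08 for the basal and 0.06 for the differentiation list. These list medians near 0 thus passed by lying below random lists above 0, not by a clear fall. Leukocyte markers had 3 of 4 up and 0 down (3 and 0 adjusted over the list alone; median 0.52, adjusted p = 0.00874): CD14, which is also on the VDR target list, CD68 at 0.31 and ITGAM at 0.73 in the authors' deposited table.

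Genes called with IL-13 and with vitamin D, each against the same untreated libraries, overlapped in both directions. Of 14734 genes tested throughout, 883 changed in the same direction and 1275 in opposite directions, where independent lists give 654 and 660. DHRS9, SERPINB1 and IVL fell with IL-13 and rose with vitamin D, SERPINB3 rose with IL-13 and fell with vitamin D, and KRT10 and DSG1 fell with both in the authors' deposited tables. The covariance of the fold changes across genes was -0.00461, against 0.00905 simulated for unchanged groups with shared controls. Those simulations held no changed gene, so few calls were bound to follow. They gave 0.01 genes per draw called in the same direction and 0 in opposite directions, which does not gauge the shared calls. Independent lists take every gene as equally likely to be called, which was not tested, so the excess over them is not exact. Part of the excess in the same direction may come from the shared untreated libraries, which push both fold changes the same way and so do not give the excess in opposite directions. They could not be split because the tables hold 1 value per group.

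In cells given both treatments, compared with untreated cells, genes of both responses stood among the largest rises. In the authors' deposited table CYP24A1 rose by 9.69, TNFAIP6 by 7.63 and CD14 by 6.21. The 4 tables disagree by 6.14 for TNFAIP6: both against vitamin D is listed as 1.32 where the log2 ratio of RPKM with a pseudocount of 0.1 is 7.55, while the 7.63 against untreated stands beside a ratio of 7.87. In the authors' deposited table CAPN14 rose by 5.48, from 10.2 to 463 RPKM, the collagen gene COL13A1 by 5.43 and CCL26 by 5.09 (adjusted p = 2.38e-99). The RPKM ratio of CCL26 with a pseudocount of 0.1 was 6.37, so its size is uncertain here too. RPTN at 3.82, SERPINB4 at 3.36 and CISH at 2.79 also rose in the authors' deposited table. VWF at 2.56, SOCS1 at 2.10, SERPINB1 at 1.69, CDH3 at 0.96 and SERPINB3 at 0.53 also rose in the authors' deposited table. Falls in the authors' deposited table were led by ADH7 at -2.99, KRT1 at -2.74, ENDOU at -2.73, CYP2C18 at -2.71, ZBTB7C at -2.59 and DSG1 at -2.43, with KRT10 at -2.25. STAT6 changed by -0.30, while VDR at 0.10 (adjusted p = 0.157) and IL13RA2 at 0.52 (adjusted p = 0.0808) did not pass in the authors' deposited table. In total 5063 of 15971 tested genes passed in the authors' deposited table, 2549 higher and 2514 lower. Of these 292 rose and 231 fell by at least 2-fold. Of all called genes 2424 were called in the same direction with IL-13 alone and 2462 with vitamin D alone over the 14734 genes, where independent lists give 669 and 826. These pairs share the untreated libraries, and simulated covariances of 0.00905 and 0.00902 stood against 0.0751 and 0.0875 in the data.

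With both treatments the IL-13 response list had 18 of 24 members up and 2 down (19 and 2 adjusted over the list alone; median 1.47), and VDR targets 26 of 31 up and 3 down (26 and 3 adjusted over the list alone; median 0.74). Differentiation genes had 7 of 54 up and 37 down (7 and 37 adjusted over the list alone; median -0.60), and interferon genes 2 of 32 up and 23 down (3 and 25 adjusted over the list alone; median -0.32). NF-kappaB genes had 2 of 23 up and 13 down (2 and 16 adjusted over the list alone; median -0.32). Each of these medians had a permutation adjusted p of 0.000486. Protease genes had a median of -0.11 (permutation adjusted p = 0.00793) and a mean of 0.11 (9 up and 16 down of 39, as adjusted over the list alone). Cytokines had 11 of 45 up and 15 down (11 and 16 adjusted over the list alone; median -0.25, permutation adjusted p = 0.000486, and 0.983 for the mean). Cell cycle genes had 4 of 38 up and 9 down, also over the list alone (median -0.18, permutation adjusted p = 0.016, and 0.17 for the mean). Cholesterol synthesis had 3 of 22 up and 13 down (4 and 15 adjusted over the list alone; median -0.19, permutation adjusted p = 0.00085). In the authors' deposited table IFIT1 stood at -0.91, XAF1 at -0.73 and BIRC3 at -1.53. Leukocyte markers had 4 of 6 up and 0 down (4 and 0 adjusted over the list alone; median 0.71, adjusted p = 0.000486), CD14, ITGAM at 1.27, ITGAX at 1.13 and CD68 at 0.15 in the authors' deposited table. Endothelial markers had 2 of 5 up, VWF and CLDN5 at 3.24 in the authors' deposited table (2 and 0 adjusted over the list alone; median 0.11, adjusted p = 0.303).

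The design also asks whether the IL-13 response differed in the presence of vitamin D. Against vitamin D alone, adding IL-13 raised CAPN14 by 4.87, CCL26 by 4.47, RASGRP1 by 4.44, SERPINB4 by 4.26 and FAM26E by 3.81 in the authors' deposited table. RPTN rose by 2.62, CISH by 2.60, SERPINB3 by 2.5, SOCS1 by 1.76, SOX2 by 1.57, VWF by 1.33, DSC3 by 0.74 and CDH3 by 0.65 in the authors' deposited table. ENDOU at -2.58, DHRS9 at -2.31, IVL at -2.11, RHOF at -1.97, ADRA1B at -1.87, PLA2G4D at -1.83, the transglutaminase gene TGM1 at -1.21, SERPINB1 at -1.01 and CYP24A1 at -0.31 (adjusted p = 4.01e-17) fell in the authors' deposited table. Of 14859 tested genes 4936 passed in the authors' deposited table, 2432 higher and 2504 lower. Of these 164 rose and 76 fell by at least 2-fold.

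In that comparison the IL-13 response list had 19 of 24 up and 1 down (20 and 1 adjusted over the list alone; median 1.38). Differentiation genes had 3 of 52 up and 37 down (3 and 42 adjusted over the list alone; median -0.46) and interferon genes 3 of 32 up and 18 down (3 and 19 adjusted over the list alone; median -0.21). These 3 lists each had an adjusted p of 0.00085. Proteases had 7 of 39 up and 22 down (7 and 23 adjusted over the list alone), with a median of -0.25 (permutation adjusted p = 0.00085) and a mean of 0.06. VDR targets had 9 of 31 up and 13 down (9 and 15 adjusted over the list alone; median -0.17, permutation adjusted p = 0.0085, and 0.487 for the mean). Cytokines had 5 of 43 up and 12 down (5 and 14 adjusted over the list alone; median -0.15, permutation adjusted p = 0.00272, and 0.982 for the mean). Immediate early genes had 1 of 32 up and 15 down (2 and 16 adjusted over the list alone; median -0.12, permutation adjusted p = 0.0348). Leukocyte markers had 1 of 4 up and 1 down, also over the list alone (median 0.34, permutation adjusted p = 0.017, and 0.118 for the mean). Of 112 genes that rose at least 2-fold with IL-13 alone and were tested throughout, 110 also passed in the same direction with vitamin D present, with medians of 1.44 and 1.40. Of 59 that fell at least 2-fold, 58 did so, with medians of -1.20 and -1.07. Across 14734 genes, 3009 were called in the same direction in both IL-13 comparisons and 10 in opposite directions, where independent lists give 660 and 658, and the fold changes, which share no library, had a Pearson r of 0.836 across genes.

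The difference between the IL-13 effects with and without vitamin D, which equals the difference between the vitamin D effects, was tested per gene from the authors' deposited tables. It passed for 357 of 14734 genes, 208 higher and 149 lower (z test, Benjamini-Hochberg adjusted). TGM2, which encodes a protein-crosslinking transglutaminase, had a difference of 1.27 ± 0.09 (SE; adjusted p = 4.01e-46) derived from the authors' deposited tables. It stood at 6.56 RPKM untreated, 14.6 with IL-13, 2.77 with vitamin D and 15.0 with both. The growth factor gene HBEGF had a difference of 1.33 ± 0.09 (adjusted p = 1.39e-45) derived from the authors' deposited tables. It stood at 8.05, 5.64, 12 and 21.9 RPKM in the same order. CEACAM6 at 1.06 ± 0.09, SOX2 at 1.03 ± 0.10, TMEM97 at 1.01 ± 0.10, THBS1 at 0.69 ± 0.05 and SERPINB3 at 0.68 ± 0.08 were also higher. Lower differences were found for ADAMTS15 at -0.85 ± 0.08, CILP at -0.88 ± 0.10, GRK5 at -0.61 ± 0.08 and the carbonic anhydrase gene CA2 at -0.48 ± 0.06. The transcripts KRT16P2 at -1.10 and KRT16P3 at -1.12 are keratin 16 pseudogenes that share reads with their parent and are uncertain. Derived from the authors' deposited tables in the same way, CAPN14 at -0.21 ± 0.19 (adjusted p = 0.814), CISH at 0.11 ± 0.10, CYP24A1 at 0.25 ± 0.19, VDR at 0.03 ± 0.07, STAT6 at -0.01 ± 0.06 and IL13RA2 at -0.20 ± 0.28 did not pass, and CCL26 was not tested. For CAPN14 and CISH a table lists p as 0, so these errors are upper bounds and leave open whether the effects differed.

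Of those 357 genes, 108 rose and 85 fell with IL-13 in both settings, 67 rose and 45 fell only in the tables with vitamin D, 18 rose and 24 fell only in those without, and 10 changed direction, 8 from a fall to a rise and 2 from a rise to a fall. Among the IL-13 risers of at least 2-fold, 31 differed, 13 with a smaller and 18 with a larger response. The interferon list was lower as a group (0 up and 3 down of 32; 1 and 8 adjusted over the list alone; median -0.15, permutation adjusted p = 0.0034), with MX1 at -0.22 ± 0.06. Differentiation genes (4 up and 5 down of 52; 6 and 10 adjusted over the list alone) had a median of -0.10 (permutation adjusted p = 0.0034), and VDR targets (2 up and 1 down of 28; 2 and 3 adjusted over the list alone) a median of -0.10 (permutation adjusted p = 0.00748). The means of these 2 lists did not pass (permutation adjusted p = 0.491 each). The basal epithelial list had a small median of 0.05, above its random lists (-0.04; permutation adjusted p = 0.00748). Of its 20 members 2 were up and 0 down, as adjusted over the list alone, and 18 were not called. Medians and means also passed for cell cycle (1 up and 0 down of 37, also over the list alone; median 0.09, permutation adjusted p = 0.0446) and cytokines (4 up and 0 down of 40; 6 and 0 adjusted over the list alone; median 0.07, permutation adjusted p = 0.045). Over members at 1 RPKM or more neither of these 2 lists passed (permutation adjusted p = 0.0626 each). The median but not the mean passed for endothelial markers (0 up and 1 down of 4, also over the list alone; median -0.43, permutation adjusted p = 0.0034). So it did for leukocyte markers (0 up and 0 down of 3, also over the list alone; median 0.25, permutation adjusted p = 0.0295) and cholesterol synthesis (1 up and 0 down of 22; 2 and 1 adjusted over the list alone; median 0.03, permutation adjusted p = 0.0446). The mean but not the median passed for cell junctions (7 up and 2 down of 30; 9 and 2 adjusted over the list alone; permutation adjusted p = 0.00113 and 0.0636). In simulated data of 14734 genes the test recovered 58% of changes of 0.5 and 84% of changes of 1 on the log2 scale. With standard errors 1.5 times as large, 56 genes passed.

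**Figure D2:**
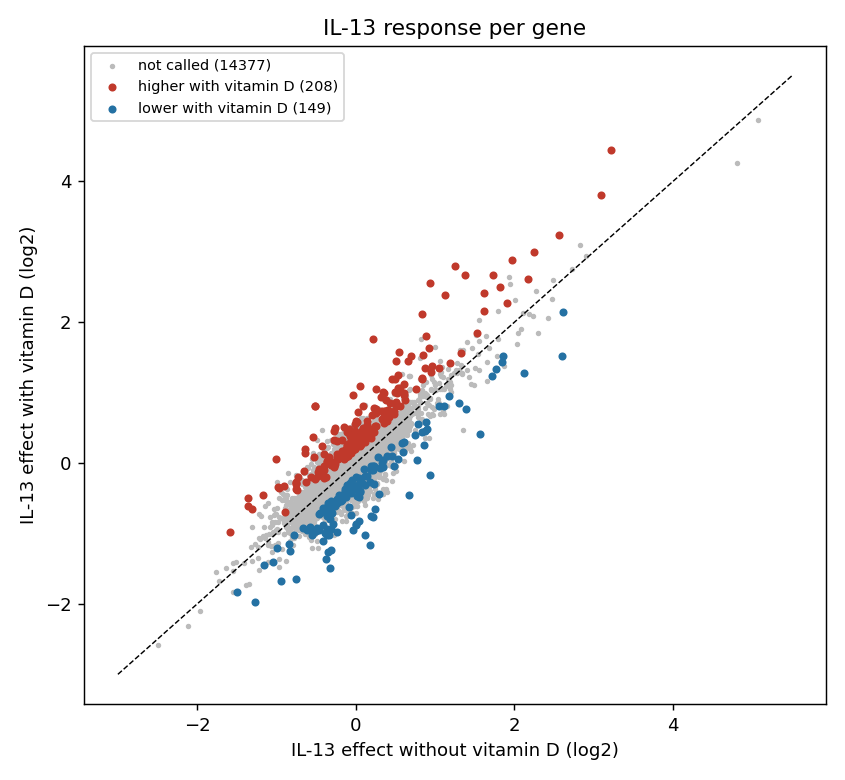
The IL-13 effect on each of 14734 genes without vitamin D (x axis, log2) and with vitamin D (y axis, log2), from the authors' deposited tables; the dashed line marks equal effects. Coloured points are the 208 genes with a higher and the 149 with a lower effect in the presence of vitamin D, and the genes follow the line with an r of 0.836.

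The last RNA comparison asked what vitamin D changed in cells given IL-13. No table used here held it directly, so it was derived from the authors' deposited tables, with standard errors that are themselves derived. CYP24A1 was 10.25 ± 0.21 (SE) higher on the log2 scale, CD14 5.81 ± 0.13, KLK6 3.01 ± 0.11, FOS 2.80 ± 0.13, SERPINB1 2.59 ± 0.05, EFTUD1 2.33 ± 0.06 and KRT4 2.21 ± 0.05. For these genes p is listed as 0 for vitamin D against untreated, whose variance is subtracted, so their errors may be too small or too large. HBEGF at 1.95, NET1 at 1.67, CRNN at 1.40, IL1B at 1.32, TGFB1 at 1.29, EMP1 at 0.90 and KLK7 at 0.85 also rose. The chemokine gene CXCL14 at -1.77 ± 0.09, DSG1 at -1.45 ± 0.06, KRT1 at -1.42 ± 0.07, CNTNAP2 at -1.41 ± 0.06, SERPINB3 at -1.29 ± 0.06 and the glucocorticoid-induced gene TSC22D3 at -1.28 ± 0.05 fell. Of the genes always named, also derived from the authors' deposited tables, CAPN14 at 0.40 ± 0.18 (adjusted p = 0.101) and IL13RA2 at -0.15 ± 0.21 did not pass. The error of CAPN14 comes from tables that list p as 0 and may be too large, so a difference between 358 and 463 RPKM is not excluded. CISH rose by 0.30 ± 0.08 (adjusted p = 0.000609), and VDR at -0.18 ± 0.06 and STAT6 at -0.13 ± 0.05 (adjusted p = 0.0494) fell in these values from the authors' deposited tables. CCL26 was not tested there.

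Of 14734 genes 3555 passed, 1808 higher and 1747 lower. Of these 166 rose and 82 fell by at least 2-fold. VDR targets had 21 of 28 up and 3 down (22 and 3 adjusted over the list alone; median 0.70). Interferon genes had 1 of 32 up and 21 down (1 and 21 adjusted over the list alone; median -0.25), and NF-kappaB genes 3 of 23 up and 12 down (3 and 14 adjusted over the list alone; median -0.22). Differentiation genes had 13 of 52 up and 21 down (15 and 22 adjusted over the list alone; median -0.10) and immediate early genes 15 of 32 up and 9 down (15 and 9 adjusted over the list alone; median 0.16). These 5 lists each had a permutation adjusted p of 0.00068. The means of the last 2 lists did not pass, with an adjusted p of 0.151 each. The IL-13 response list had 5 of 20 up and 8 down (6 and 9 adjusted over the list alone) with a median of -0.07 (permutation adjusted p = 0.217), and its mean of -0.20 passed (adjusted p = 0.0211). Cholesterol synthesis had 4 of 22 up and 7 down (5 and 8 adjusted over the list alone; median -0.08, permutation adjusted p = 0.00826, and 0.255 for the mean). Leukocyte markers had 3 of 3 up, also over the list alone (median 1.31, permutation adjusted p = 0.00113). Of the genes called with IL-13 alone, 1036 moved in the opposite direction when vitamin D was added and 746 in the same direction, where independent lists give 478 and 477. Both comparisons hold the IL-13 libraries: the covariance of the fold changes was -0.00572, against -0.00405 simulated for unchanged groups that share them. Part of the opposite movement may therefore come from the shared libraries. The vitamin D effects with and without IL-13, which share no library, had 2748 calls in the same direction, 17 in opposite directions and a Pearson r of 0.848 across genes.

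STAT6 binding was profiled to ask where the factor lies after IL-13. The untreated library held 1126 regions and the IL-13 library 4802, of which 913 overlapped an untreated region and 3889 did not. At a fold enrichment of at least 5 they held 931 and 2250, 1590 of the latter without an untreated overlap. All ChIP conditions have 1 library, so differences between them have no replicate check, and pileups, fold enrichments and q-values are the authors' peak caller's own scores. The IL-13-only regions of largest fold enrichment lay in an exon of SLC22A5, a carnitine transporter gene (chromosome 5, 131724000 to 131726335, 29.2-fold), in an intron of a gene whose symbol the list holds as a date (chromosome 9, 117928579 to 117930301, 25.9-fold), and between genes beside HSP90AB2P (chromosome 4, 11701438 to 11703317, 25-fold) and AUH (chromosome 9, 93954651 to 93956098, 24.7-fold). Another lay upstream of MAPKAPK3 (chromosome 3, 50638015 to 50639748, 24.5-fold), within 10 kb of the start of CISH.

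Of 26 genes named in the IL-13 comparison, 12 were assigned 15 STAT6 regions, all absent from the untreated list. They included the SOCS1 promoter (chromosome 16, 11350124 to 11351387, 15.3-fold), a site upstream of PKP2 (chromosome 12, 33053929 to 33055374, 15.6-fold), and a VWF intron (chromosome 12, 6187453 to 6188608, 11.1-fold). Another lay in a VDR intron (chromosome 12, 48261234 to 48261957, 8.90-fold). Weaker regions lay at the CAPN14 promoter (chromosome 2, 31440418 to 31440654) and in CCL26 (chromosome 7, 75401592 to 75401878), each at 4.20-fold. The authors' list places the CCL26 region at a promoter, but it lies over 10 kb inside the gene from the start used here, so CCL26 counts below as having 0 STAT6 regions. Of the IL-13 regions 52.1% overlapped an H3K27ac region of the IL-13 library and 4.87% lay in promoters. The IL-13 library had the higher background, 3.05 against 1.46 fragments, so an effect of depth on these numbers is not excluded. In the 913 shared regions the median log2 ratio of fold enrichment was -0.21.

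VDR regions numbered 1828 without and 9224 with vitamin D, of which 1571 overlapped an untreated region and 7653 did not. In the shared regions the median log2 ratio of fold enrichment, vitamin D over untreated, was 1.31. The vitamin D library had been scaled, while the untreated one held whole-number pileups. An effect of this on the numbers of regions and on the ratio is not excluded. The strongest regions seen with vitamin D and not untreated lay near DEFB135 (chromosome 8, 11751406 to 11752524, 54.9-fold) and the E-cadherin gene CDH1 (chromosome 16, 68741000 to 68742288, 45.9-fold). The next 3 lay near PTP4A1 (chromosome 6, 64232260 to 64233394, 42.9-fold), KPNA7 (chromosome 7, 98821698 to 98822968, 42.9-fold) and BTBD11, in an intron (chromosome 12, 107830172 to 107831447, 39.3-fold).

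Of 27 genes named in the vitamin D comparison, 17 were assigned 48 VDR regions, 29 of them absent from the untreated list. The highest stood beyond CYP24A1 (chromosome 20, 52739601 to 52741259, 111-fold), with another at its promoter (52790132 to 52791434, 23.9-fold), both also called untreated. Others lay near FOS (chromosome 14, 75720591 to 75722324, 84.1-fold) and SERPINB1 (chromosome 6, 2790979 to 2792284, 77.3-fold, and its promoter, 2843072 to 2844226, 34.1-fold). Further regions lay near EMP1 (chromosome 12, 13326268 to 13327300, 52.2-fold), PTPN1 (chromosome 20, 49114089 to 49115326, 51.5-fold) and at the CD14 promoter (chromosome 5, 140012445 to 140013398, 26.1-fold). H3K27ac regions of the vitamin D library overlapped 65.9% of the VDR regions with vitamin D, and 13.3% of these VDR regions lay in promoters.

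**Figure D3:**
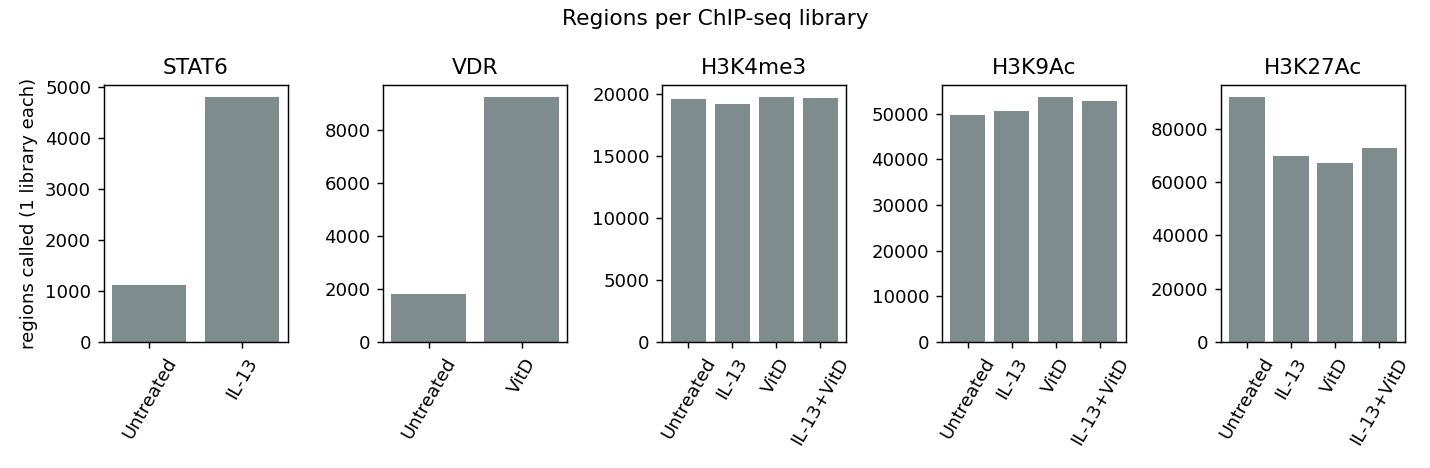
Regions called in each ChIP-seq library (y axis, number of regions) by treatment (x axis), with a separate scale per factor or mark and 1 library per bar. STAT6 goes from 1126 to 4802 regions with IL-13 and VDR from 1828 to 9224 with vitamin D, and H3K27ac has 91881 regions untreated. The VDR library with vitamin D had been scaled and the untreated one had not.

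Binding and RNA were joined by asking whether genes that changed had a region within 10 kb of their start. Of 1732 genes that rose with IL-13 and reached 1 RPKM, 183 (10.6%) had a STAT6 region, against 261 of 7750 genes not called (3.37%; odds ratio 3.39, two-sided Fisher's exact test p = 7.74e-31, adjusted 2.32e-30 over 12 tests). Of those that rose at least 2-fold, 26 of 94 had one (odds ratio 11). Genes that fell with IL-13 had one in 4.33% of cases (odds ratio 1.30, Fisher's exact test p = 0.0458, adjusted 0.055). Of 2449 genes that rose with vitamin D, 863 (35.2%) had a VDR region, against 954 of 6888 not called (13.9%; odds ratio 3.38, Fisher's exact test p = 4.07e-107, adjusted 4.88e-106), and 82 of 150 that rose at least 2-fold had one (odds ratio 7.50). Genes that fell with vitamin D had one in 12.8% of cases (odds ratio 0.912, Fisher's exact test p = 0.225). These tests run across genes, which are not independent replicates.

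VDR regions, measured with vitamin D, also lay beside 530 of 1918 genes that fell with IL-13 (27.6%, against 16.1% of genes not called; odds ratio 1.99, Fisher's exact test p = 3.6e-29, adjusted 8.63e-29), and beside 16.2% of genes that rose (odds ratio 1.00, p = 0.942). STAT6 regions lay beside 6.04% of the genes that rose and 6.05% of those that fell with vitamin D, against 3.59% not called (odds ratio 1.73 each, Fisher's exact test, adjusted p = 1.17e-06 and 4.31e-06). For the combination against untreated, STAT6 had an odds ratio of 3.30 and VDR of 2.31 beside genes that rose (Fisher's exact test, adjusted p = 5.28e-32 and 9.39e-46), and 1.40 and 1.35 beside genes that fell (adjusted p = 0.0128 and 8.85e-06).

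**Figure D4:**
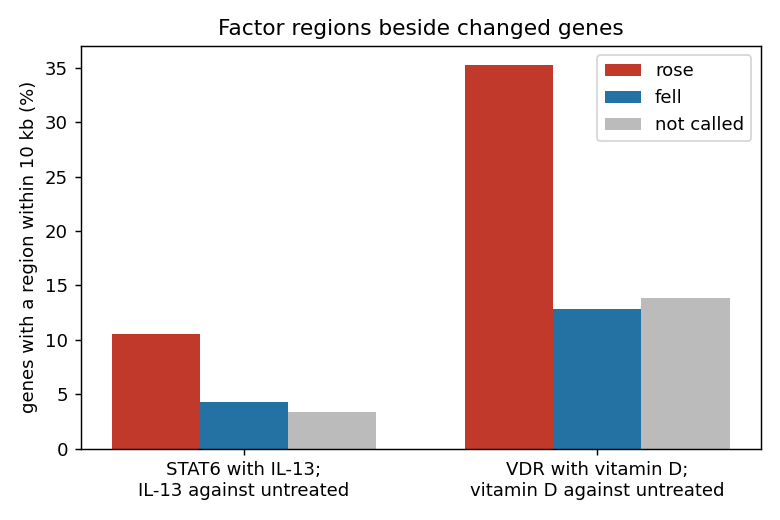
Percent of genes at 1 RPKM or more with a region of the factor within 10 kb of the start (y axis), for genes that rose, fell or were not called in the comparison named below each set of bars. STAT6 regions lie beside 10.6% of genes that rose and 3.37% of those not called with IL-13, and VDR regions beside 35.2% and 13.9% with vitamin D.

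STAT6 regions of the IL-13 library and VDR regions of the vitamin D library overlapped at 312 of 4802 STAT6 regions (6.5%). The sites included exons of NOD2, an intracellular pattern receptor gene (chromosome 16, 50733266 to 50734907, STAT6 21.3-fold), and ARHGEF37 (chromosome 5, 148998201 to 148999279, 20-fold). Others were an intron of VMP1 (chromosome 17, 57863411 to 57864851, 19.5-fold) and a site upstream of the protease gene TMPRSS13 (chromosome 11, 117817151 to 117818379, 19.3-fold). These sites were picked after their values were seen. Over 100632 H3K27ac regions, 423 held both factors, where 202 would if the factors were independent and all regions equally likely to hold them (odds ratio 2.35, two-sided Fisher's exact test p = 3.66e-47, across regions). The regions were not matched on length or height, so an effect of these is not excluded. Over 21149 H3K4me3 regions the odds ratio was 1.22 (Fisher's exact test p = 0.0935).

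Histone marks were compared between single libraries. H3K4me3 had 19605, 19160, 19740 and 19683 regions in untreated, IL-13, vitamin D and combined libraries, and H3K9ac had 49647, 50695, 53630 and 52749. H3K27ac had 91881, 69707, 67183 and 72629. Of the untreated H3K4me3 regions 88.0% were called again with IL-13, 93.5% with vitamin D and 93.0% with both; for H3K27ac these shares were 48.2%, 51.7% and 50.8%. The H3K27ac background was 1.40 fragments in the untreated library and 0.51, 0.73 and 0.57 in the treated ones, and pileups are not scaled to a common depth. SERPINB4 had 0 H3K27ac regions untreated and with vitamin D, 4 with IL-13 and 2 with both. In the order untreated, IL-13, vitamin D and both, CAPN14 had 2, 2, 1 and 4 H3K27ac regions and SOCS1 had 3, 3, 4 and 3. The highest fold enrichment in the authors' lists went from 12.1 untreated to 5.29 with IL-13 at CAPN14, and from 21.3 to 24.5 at SOCS1. As pileup over background these were 20.1 and 13.7, and 35.8 and 70.3, so the size of the change depends on the scaling. The other marks at CAPN14 were near the limit of calling, with highest pileups of 5 with IL-13 and 7 with both for H3K4me3. For H3K9ac they were 6 with IL-13 and 4 with vitamin D. The smallest heights called in these libraries were 4 or 5, so the numbers of regions do not show a change. In the order untreated, IL-13, vitamin D and both, H3K4me3 regions at CAPN14 numbered 0, 2, 0 and 2, and H3K9ac regions 0, 2, 1 and 0. At CYP24A1 H3K27ac regions numbered 5 untreated, 1 with IL-13, 8 with vitamin D and 9 with both, and H3K9ac regions 1, 0, 5 and 6.

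After dividing pileup ratios by the median over shared regions, H3K27ac at regions that overlapped STAT6 was 0.22 on the log2 scale above untreated with IL-13, where matched random sets gave -0.02. It was 0.24 with both (matched sets -0.03) and 0.00 with vitamin D (matched sets -0.05), so it lay above its sets with vitamin D alone as well. H3K9ac there was 0.19 with IL-13 (matched sets 0.00, or 0.15 when matched on treated pileup, two-sided share 0.0404), 0.17 with both (matched sets 0.00) and 0.01 with vitamin D (matched sets -0.14), so its excess over matched sets was not particular to IL-13. H3K4me3 there was -0.03 with IL-13 (matched sets -0.02; two-sided share 0.212), 0.12 with both (matched sets 0.02) and -0.02 with vitamin D, below its matched sets (0.03; two-sided share 0.001). At VDR regions H3K27ac was 0.11 with vitamin D (matched sets -0.03), 0.07 with both (matched sets -0.04) and -0.09 with IL-13 (matched sets -0.07), and H3K4me3 was -0.02 with vitamin D (matched sets -0.03; two-sided share 0.206). The H3K27ac values, and H3K9ac at STAT6, lay outside all 10000 matched sets, a two-sided share of 0.0002 and the smallest these sets can give. H3K9ac at VDR regions was 0.03 with vitamin D, above its sets matched on untreated pileup (-0.14) and below those matched on treated pileup (0.06), and 0.00 with IL-13 and with both (matched sets 0.00). All of this describes single libraries. H3K9ac heights were small whole numbers, with medians of 6 or 7, so its ratios take few values.

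At the starts of genes that rose at least 2-fold, scaled H3K27ac was 0.19 higher with IL-13 over 64 genes, 0.19 with vitamin D over 112 genes and 0.23 with both over 161 genes. At genes that fell at least 2-fold it was -0.27 over 21 genes, -0.19 over 35 and -0.29 over 97. Matched sets of genes had medians between -0.04 and 0.00, and these 6 medians had adjusted two-sided shares of 0.0357 or less over 18 sets. H3K4me3 was 0.12, 0.17 and 0.19 higher at the genes that rose in the same 3 comparisons, and -0.02, -0.02 and -0.08 at those that fell, of which only the last passed (adjusted shares 0.898, 0.15 and 0.0006). H3K9ac did not pass at genes that rose (0.00, 0.00 and 0.12; adjusted shares 1, 0.16 and 0.0876). At genes that fell it was 0.00, -0.14 and -0.19 (adjusted shares 1, 0.898 and 0.00225). H3K9ac heights were whole numbers, with medians of 6 or 7 and a smallest of 4, so their ratios take few values. With IL-13 the genes that rose and their random sets both had a median of 0.00. A lack of change in H3K9ac is therefore not shown.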

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

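The tests of the first 2 patterns below, and the stratified test of H3K27ac, were written after the results had been seen, and the other tests before.

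Of the untreated STAT6 regions 22.3% (251 of 1126) lay inside regions of all 3 histone marks, against 5.84% of the IL-13-only regions. Regions that draw reads in every library would give such a difference, so they may account for that part of the untreated list. VDR regions went the other way: 0.444% of the untreated STAT6 regions lay in one, against 7.87% of the IL-13-only regions. That VDR list came from a scaled library and held 0 mitochondrial peaks, against 47 and 49 in the STAT6 lists. It was thus made differently, so its shares do not count for or against the explanation, which stays open. The rest of the untreated regions are not explained by this test. The untreated regions were intergenic in 74.0% of cases and the IL-13-only regions in 47.3%, a difference that was not tested.

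The untreated H3K27ac library had more regions than any treated one. Scaled by the background ratio of 0.367, 79.4% of the regions called only there (37780 of 47582) would fall at or below the lowest heights called with IL-13, against 14.8% of the shared regions. Greater depth of the untreated library may therefore account for most of them. No loss of H3K27ac with treatment was inferred.

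VDR regions lay beside more of the genes that fell with IL-13 than of genes not called. Expression does not account for all of it: the 27.6% stood at percentile 100 of matched sets, whose median was 19.2%. Nor do genes called with vitamin D account for all of it. Among genes not called with vitamin D the odds ratio was 1.83 (95% interval 1.49 to 2.25; 143 of 660 genes). It was 1.42 (1.17 to 1.71; 296 of 727) among genes that rose with vitamin D and 1.88 (1.37 to 2.58; 91 of 531) among those that fell. Genes that rose with vitamin D may thus account for part of the excess. Among genes with an untreated H3K27ac region the odds ratio was 2.06, but 1796 of the 1918 genes that fell have one, so this does not test H3K27ac. Over 25 strata of the extent and height of H3K27ac near the gene in the 4 libraries, the Mantel-Haenszel odds ratio was 1.47 (95% interval 1.29 to 1.67), against 1.99 without strata, and 1.42 to 1.64 by library. H3K27ac may thus account for part of the excess but not, as measured here, for all of it; differences within strata stay open. As a hypothesis only, genes lowered by IL-13 may lie near enhancers that VDR can bind; testing it needs VDR libraries with IL-13 and replicates.

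The IL-13 response differed with vitamin D for 357 genes. On the log2 scale the differences were 1.27 for TGM2, 1.33 for HBEGF, 0.687 for THBS1, 1.06 for CEACAM6, 1.01 for TMEM97, 1.03 for SOX2, 0.598 for KRT10, 0.573 for CRNN, 0.679 for SERPINB3, 0.647 for DSG1, 0.389 for SPINK5, 0.374 for DSC3, 0.349 for IL1B and 0.283 for GJB6. They were -1.1 for KRT16P2, -1.12 for KRT16P3, -0.851 for ADAMTS15, -0.879 for CILP, -0.483 for CA2, -0.606 for GRK5, -0.315 for IGFBP3 and -0.566 for CASP14.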

How the results depend on the processing

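The tests with larger standard errors and those of the derived comparison were chosen after the results were seen. No paired analysis was possible because the tables hold 1 value per group and the labels pair no samples. For the same reason leaving out replicates and other splits could not be run, and the tests set down for counts or for values per sample did not apply. The motif result could not be run because no genome sequence of the build was at hand. Where a result below changed, the cause was not tested, except where one is given. Of the other settings fixed beforehand for the main results 268 gave the same result, 48 moved a count by over 1.5 times, 25 ended a call, 15 made one and 8 reversed a direction; of those added later 8 gave the same result and 1 moved. Named genes kept their size with RPKM ratios and a pseudocount of 0.1 in 107 results and moved in 36; with a pseudocount of 1 these were 58 and 85.

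With a change of at least 2-fold, genes called numbered 181 with IL-13, 258 with vitamin D, 523 with both, 240 for both against vitamin D and 248 for both against IL-13. IL-13 genes of at least 2-fold moved in the opposite direction under added vitamin D in 64 cases and in the same direction in 51. They shared 46 calls with vitamin D in the same direction and 67 in the opposite one, and 157 with the combination; vitamin D genes of at least 2-fold shared 226 with the combination. With standard errors 1.5 times as large the difference of IL-13 effects passed for 56 genes.

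With the mean in place of the median, 7 lists passed with IL-13 and 5 for the difference of effects. With IL-13 the means were 0.17 for the receptor and JAK-STAT list and 0.10 for proteases, both reversed in sign, and -0.0757 for junctions, -0.0915 for cytokines, -0.0471 for interferon and -0.15 for cholesterol synthesis, which no longer passed. With vitamin D they were 0.61 for vitamin D metabolism and 0.0167 for differentiation, both reversed, -0.25 for the IL-13 response and -0.0784 for junctions, which now passed, and 0.22 for immediate early genes, which did not. With both they were 0.68 for vitamin D metabolism, 0.23 for JAK-STAT and 1.13 for endothelial markers, which now passed, 0.11 for proteases, reversed, and -0.0249 for cytokines and -0.16 for cell cycle, which did not pass. For both against vitamin D they were -0.0789 for VDR targets, -0.00877 for cytokines and 0.30 for leukocyte markers, which did not pass, 0.20 for JAK-STAT and 0.64 for endothelial markers, which did, and 0.0585 for proteases, reversed. For both against IL-13 they were -0.20 for the IL-13 response and 0.65 for vitamin D metabolism, which passed, and -0.0476 for differentiation, -0.041 for cholesterol synthesis and 0.13 for immediate early genes, which did not. For the difference of effects they were 0.0768 for junctions, which passed, and -0.0343 for VDR targets, -0.0333 for differentiation, 0.0165 for cholesterol synthesis, 0.17 for leukocyte and -0.26 for endothelial markers, which did not.

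Over members at 1 RPKM or more, the medians were -0.0491 for junctions with IL-13 and -0.16 for cell cycle with both, which did not pass, -0.11 for the IL-13 response in both against IL-13 and 0.0824 for it in the difference of effects, which passed, and 0.0673 for cytokines and 0.0905 for cell cycle in the difference of effects, which did not.

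At a fold enrichment of at least 5, STAT6 had 931 regions untreated and 2250 with IL-13, 1590 of them new, a ratio of 2.42 in place of 4.26. At a -log10 q of at least 5 it had 810 and 2791, 2115 of them new. Among the 1000 of largest fold enrichment 584 were new and 497 untreated regions were shared; these are most of the 1126 untreated regions but a small part of the 4802 with IL-13, so their ranks do not show a change. VDR at a -log10 q of at least 5 had 1055 untreated regions, 1005 of them shared; among the top 1000, 333 were new and 676 untreated regions were shared. The odds ratio of STAT6 regions beside genes that fell with IL-13 was 1.23 within 2 kb, 0.994 at a fold enrichment of at least 5 and 1.25 for falls of at least 2-fold. It was 1.27 within 50 kb (Fisher's exact test p = 0.00142) and 1.37 for regions absent from the untreated library (Fisher's exact test p = 0.0191). That of VDR beside genes that fell with vitamin D was 0.800 within 50 kb. STAT6 regions that overlapped VDR numbered 153 at a fold enrichment of at least 5, and the odds ratio over H3K4me3 regions was 1.22.

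Shared histone regions at least 2-fold apart from untreated, in the order IL-13, vitamin D and both, numbered 213, 404 and 379 for H3K4me3, 546, 447 and 380 for H3K9ac and 446, 460 and 615 for H3K27ac at a fold enrichment of at least 5. With no scaling they numbered 1626 with vitamin D and 1544 with both for H3K4me3, 2618 with vitamin D for H3K9ac, and 31395, 13938 and 29635 for H3K27ac. H3K9ac regions at a fold enrichment of at least 5 numbered 34546 untreated and 24244, 26101 and 25318 in the treated libraries. Untreated ones shared with them numbered 19992, 22080 and 20865. The untreated library thus held the most regions instead of the fewest. Its background was the lowest, 0.389 against 0.485, 0.469 and 0.466. At a height of 6 the treated libraries gave a fold enrichment of 4.71, 4.77 and 4.78, so the cutoff passes that height only in the untreated library. The reversal therefore does not show a change in the mark. H3K27ac regions numbered 47556 untreated, 40607 with IL-13, 45038 with vitamin D and 42148 with both. H3K4me3 at STAT6 regions with IL-13 was -0.0733 for factor regions at a fold enrichment of at least 5 and -0.0337 when matched on treated pileup, and both lay outside the middle 95% of matched sets. H3K9ac at VDR regions was 0.0324 when matched on treated pileup, below its sets.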

Other observations

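As a list, the receptor and JAK-STAT genes did not pass with vitamin D (4 up and 6 down of 24, as adjusted over the list alone; median -0.01, permutation adjusted p = 0.638). In the authors' deposited table the receptor gene IL4R rose by 0.72 (adjusted p = 4.13e-93) and PTPN1, which encodes a tyrosine phosphatase, by 0.89 with vitamin D, and IL4R changed by -0.22 with IL-13. The vitamin D activating enzyme gene CYP27B1 rose by 1.19 (adjusted p = 1.58e-34) with IL-13 in the authors' deposited table. The antimicrobial peptide gene CAMP, a VDR target, was 2.5 higher on the log2 scale with both than with IL-13 (adjusted p = 1.19e-37), derived from the authors' deposited tables. Among cell cycle genes CDC45 rose by 0.89 with IL-13 while E2F1 changed by -0.74 in the authors' deposited table.

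Regions of H3K27ac called with IL-13 and not in untreated cells held a STAT6 region in 5.52% of cases (300 of 5436), against 3.74% of shared regions (odds ratio 1.5, two-sided Fisher's exact test p = 7.09e-10, adjusted 1.7e-09 over 12 tests across regions). They held a VDR region of the vitamin D library in 1.18% of cases, against 7.84% (odds ratio 0.140, Fisher's exact test, adjusted p = 4.78e-105). H3K27ac regions called only with vitamin D held a VDR region in 8.38% of cases, against 8.94% (odds ratio 0.932, Fisher's exact test p = 0.209). They held a STAT6 region of the IL-13 library in 1.38% of cases, against 3.47% (odds ratio 0.389, Fisher's exact test, adjusted p = 4.87e-17). A low share of the other treatment's factor was thus not particular to IL-13. Regions were not matched on length or height, so an effect of these is not excluded. Each mark has 1 library per treatment, and these tests were chosen after the regions were seen.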
